A study of Homo sapiens with 6 samples.

How the data were processed

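RNA from frozen K562 cells that had been retrovirally transduced with a LIN28B shRNA or a non-targeting shRNA and selected with puromycin was hybridised, per the labels, to single-colour (Cy3) Agilent arrays, 3 per group. Per the file headers, the deposited scanner files hold spot intensities from Agilent Feature Extraction 10.5.1.1, in which the processed signal was background-subtracted and spatially detrended without normalization between arrays, on an array design drawn on hg19. The scanner files also hold the median intensity of each spot and of its local background, and the software's flags for spots well above background, saturated spots and outliers, per the file headers. The series matrix deposited by the authors holds 1 value per probe on a log2 scale. Its normalization is not stated, and the labels name Agilent Feature Extraction and limma as processing tools without versions or roles. Across probes, the median correlation of an array between the series matrix and the scaled signals was 0.997, and that of the group differences was 0.971, genes not being independent replicates.

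The processed signals were log2 transformed, and the 75th percentile of the spots that were not control spots was subtracted on each array, with outlier spots left out. The spots of a probe were averaged. Of 57176 probes, 27024 were well above background on all 3 arrays of at least 1 group, 250 of these lacked a value on an array because of outlier spots, and 26774 were tested. Of the tested probes 17364 had a gene symbol, for 13492 genes, from the array annotation and from a RefSeq gene table of assembly GRCh38.p14 that was used for names and for which genes neighbour each other. That table matched 25742 of 27266 probes with a RefSeq accession. No coordinates were converted. A gene was represented by its probe with the highest mean over the 6 arrays.

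Each probe was compared between the groups in limma (lmFit and eBayes, two-sided) with the group as the only term and Benjamini-Hochberg adjustment, and passed at an adjusted p under 0.05. Gene lists were tested with camera in limma (preset correlation 0.01, Benjamini-Hochberg over the lists) where at least 3 genes were measured, again with an estimated correlation, and with fry. The 32 lists hold 828 symbols, of which 821 matched a known gene, and were written, with the design and the alternative analyses, before the data were examined. They cover let-7 targets, let-7 biogenesis, imprinted genes, well-described lncRNAs, snoRNA hosts, globins and their regulators, haem, erythroid, megakaryocyte, stem, myeloid, lymphoid, fibroblast and epithelial genes, the cell cycle, histones, ribosomal proteins, MYC targets, metabolism, translation, stress responses, interferon, hypoxia and housekeeping genes. Genes to name were set by a rule beforehand: LIN28B and H19, the 8 largest rises and falls past the threshold with groups that do not overlap and signal above background on all arrays, the 4 largest such among noncoding probes, up to 4 members of each list with the smallest adjusted p, and up to 5 genes per direction that were above background in 1 group only. Any other gene named was chosen after its values were seen. For a gene above background in 1 group only, the other group's values were raised to the lowest level called above background on each array, which gives a lower bound of the fold. Single genes fixed in advance were also compared by an exact two-sided permutation test.

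No spot was saturated. For arrays, their number limits the precision. The limma and camera steps were tested on simulated data for LIN28B shRNA against control, 3 arrays against 3 and 26774 probes, with 200 changed probes, 50 of each size. The share recovered was 10% at 2-fold, 86% at 4-fold, 86% at 8-fold and 96% at 16-fold, with 13 unchanged probes called, and 1 list was called, the one that was shifted by 0.5 log2 (camera adjusted p 3.65e-15). The noise of each simulated probe had the variance that limma had already drawn towards a common value. Such variances differ less between probes than the unadjusted ones, so the shares recovered may be too high for the real arrays. The simulated probes were drawn independently, without correlation between genes or differences between slide rows. The simulation therefore cannot tell how often camera with the preset correlation calls unshifted lists of correlated genes.

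The alternatives were quantile normalization, subtraction of array medians, other filters on dim probes, the replicate number or the slide row as a block, an intensity trend with a robust prior, array weights, the series matrix values, a stricter threshold, the mean of all probes of a gene, other list tests, and each array left out in turn. Added after the data were seen were normexp background correction of the median signal (offset 50) with either scaling, the percentile taken over probes detected on all arrays, dark patches left out (spots in windows of 15 by 7 spots whose median deviation was under -0.5 log2), and control replicates 2 and 3 averaged, with and without array weights. In the fits with dark patches left out, each remaining spot also had the median deviation of its window subtracted. Normexp on the mean signal, planned, was not run because the files hold no such column, nor was a test of let-7 seed sites, since the reference held no 3' untranslated regions. All samples and both groups were used. R 4.3.3 was used with limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8), and figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.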

Results

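Gene expression was measured in K562 cells, an established human line derived from a chronic myeloid leukaemia that makes embryonic and fetal globins. The cells had received, by retrovirus, a short hairpin RNA (shRNA) against LIN28B or a non-targeting shRNA. LIN28B is an RNA-binding protein that blocks the maturation of let-7 microRNAs, and the series title names the imprinted long noncoding RNA (lncRNA) H19 as one it regulates. The comparison therefore asks which transcripts, H19 among them, differ when LIN28B is reduced. Each group had 3 samples, each on 1 single-colour array. All 6 arrays lay on 1 slide, the 3 LIN28B shRNA arrays and control replicate 1 in slide row 1, and control replicates 2 and 3 in slide row 2. The array held 57176 probes besides its control spots, of which 23042 were custom lncRNA probes. The 75th percentile of the spot intensity was 549, 531 and 524 on the LIN28B shRNA arrays and 515, 376 and 330 on the control arrays, and between 48.3% and 53.4% of the probes of an array were well above background. Patches of spots that were locally dim held 2.62% of the spots of control replicate 1 and between 0.0520% and 1.34% of those of the other arrays. Levels below are log2 signals relative to the 75th percentile of the same array, and differences are LIN28B shRNA minus control. The labels do not say that the samples of a group came from separate cultures, so the spread behind each p-value may be technical.

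LIN28B had a lower signal on all 3 LIN28B shRNA arrays than on any control array. Its level was 3.97 ± 0.22 (SD, n = 3) with the LIN28B shRNA and 5.10 ± 0.08 (SD, n = 3) with the control. The difference of -1.13 (SE 0.16) corresponds to a 2.19-fold lower signal (95% CI 1.66 to 2.88). H19, a lncRNA transcribed from the maternal allele, was also lower on all 3 LIN28B shRNA arrays, at -0.77 ± 0.91 (SD, n = 3) against 0.86 ± 0.20 (SD, n = 3) in the control. Its difference was -1.63 (SE 0.45), or 3.10-fold lower (95% CI 1.46 to 6.58). H19 stood at 0.27 on the array of LIN28B shRNA replicate 1 and at -1.21 and -1.37 on those of replicates 2 and 3. Each gene had 1 tested probe. Neither passed in limma after adjustment over all probes, with an adjusted p of 0.120 for LIN28B and 0.183 for H19. Adjusted over the list alone, meaning these 2 genes fixed in advance, limma gave 0.000772 for LIN28B and 0.00998 for H19. H19 was fixed because the series title names it, and that title may rest on these same arrays. The adjustment over 2 genes does not correct for such a choice. An exact two-sided permutation test gave p = 0.1 for each of the 2 genes, the smallest that 3 arrays against 3 allow. Of 22 alternatives, 1 brought either gene past the threshold over all probes: with array weights in limma the adjusted p was 0.0385 for LIN28B and 0.0439 for H19, in ranges of 0.0385 to 0.443 and 0.0439 to 0.461.

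**Figure D1:**
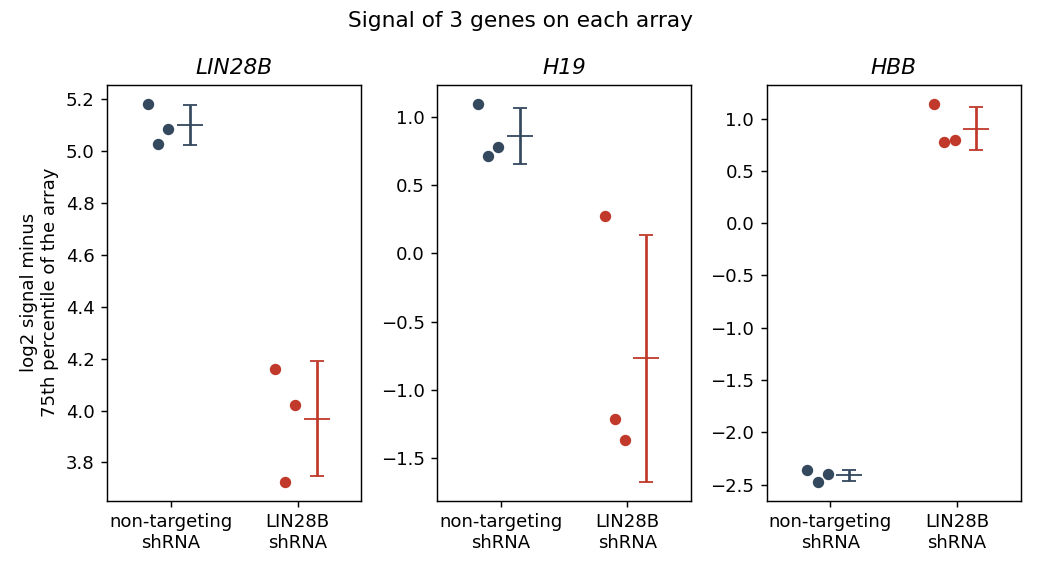
Signal of LIN28B, H19 and HBB on each array (log2 signal minus the 75th percentile of the array; each vertical axis has its own range), by shRNA, where points are arrays and bars are the mean ± SD of 3 arrays. LIN28B and H19 were lower and HBB higher on all 3 LIN28B shRNA arrays than on any control array.

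The adult beta-globin gene HBB rose 9.95-fold with the LIN28B shRNA (95% CI 7.64 to 12.96) and was the only 1 of 26774 tested probes to pass. Its level was 0.90 ± 0.21 (SD, n = 3) with the LIN28B shRNA and -2.41 ± 0.06 (SD, n = 3) with the control, higher on 3 of 3 arrays, with an adjusted p of 0.0134 in limma. The difference of gene HBB lay between 3.20 and 3.38 when any 1 array was left out, and between 2.57 and 3.44 over 22 alternatives, of which 13 kept it past the threshold. The lowest values, 2.57 and 2.65, came with normexp background correction, whose offset of 50 draws dim signals together. Its adjusted p was 0.0407 without LIN28B shRNA replicate 1, but 0.0743 without replicate 2, 0.0838 without replicate 3, and 0.0660, 0.253 and 0.129 without control replicates 1, 2 and 3, in a range of 0.00314 to 0.272 over those alternatives. It also missed the threshold with the replicate block (0.272), with control replicates 2 and 3 averaged (0.239, and 0.150 with array weights) and without a filter on dim probes (0.0794). With limma, 0 probes were lower past the threshold. At an unadjusted p under 0.05 there were 4554 probes, 2055 higher and 2499 lower, and for 26.1% of the tested probes the groups did not overlap, against 10% by chance. The split of the unadjusted probes moved with the processing, to 3135 higher and 1430 lower with array medians subtracted (which moved the median of all probes by 0.12), 2324 and 2230 with quantile normalization, 1807 and 3836 with normexp background correction of the median signal, and 2441 and 2380 with normexp and quantile normalization together. The number past the threshold depended on the arrays. Without LIN28B shRNA replicate 1 it was 26 (7 higher, 19 lower), without any other array 0 (2718 to 5070 unadjusted), with array weights 870 (389 higher, 481 lower), and with the slide row as a block 635 (588 higher, 47 lower). That block sets the 3 LIN28B shRNA arrays against control replicate 1 alone, the only control array in their slide row.

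**Figure D2:**
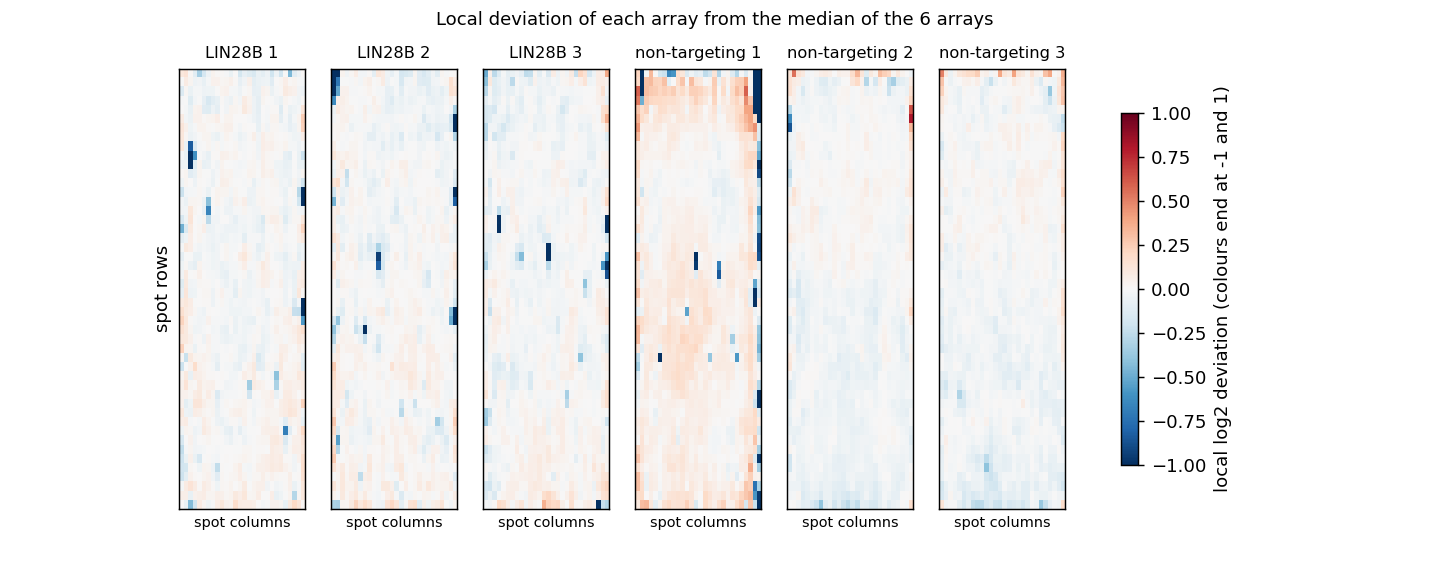
Local deviation of each array from the median of the 6 arrays (log2, colours end at -1 and 1), by spot row (vertical) and spot column (horizontal) on the array, where each cell is a median over neighbouring spots. Dark blue patches are locally dim and hold 2.62% of the spots of control replicate 1.

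Opposite to HBB, the genes of the embryonic and fetal globin list had lower estimates with the LIN28B shRNA. All 6 measured members, HBZ, HBE1, HBG1, HBQ1, HBM and HBBP1, were lower, with a median of -0.61 (1.53-fold lower). The list passed camera at an adjusted p of 0.00166. With an estimated correlation it did not hold (adjusted p = 0.693), nor by fry (adjusted p = 0.0889). With the slide row as a block, the median relative to all genes was -0.56 against -0.64 without it, and the list did not pass (adjusted p = 0.266). HBQ1, the theta-globin gene, differed by -0.82 (SE 0.20) and was the 1 member past the threshold when adjusted over the list alone (adjusted p 0.0346). In limma 0 of the 6 passed over all probes, with 3 lower at an unadjusted p under 0.05. These were HBQ1, HBE1 and HBM, the last of which differed by -0.46 (SE 0.16). HBE1, the embryonic epsilon-globin gene, differed by -0.49 (SE 0.15), and HBBP1, a beta-globin pseudogene, by -0.74 (SE 0.31), or -0.42 without LIN28B shRNA replicate 1. HBZ and HBG1 were chosen after their values were seen. HBZ, the embryonic zeta-globin gene, differed by -0.88 (SE 0.41), where LIN28B shRNA replicate 2 stood at 5.20, the other LIN28B shRNA arrays at 6.45 and 6.83, and the controls between 7.01 and 7.06. The 2 probes for HBG1, a fetal gamma-globin gene, differed by -0.45 (SE 0.24) and 0.17 (SE 0.36). At the first of these, the LIN28B shRNA arrays stood at 9.54, 9.22 and 8.93. Control replicate 1, at 9.30, lay among them, and control replicates 2 and 3 stood at 9.86 and 9.89. Among the 3 measured adult globin genes, HBA2 differed by -0.48 (SE 0.24) at its brightest probe and by -0.79 (SE 0.34) and -0.80 (SE 0.22) at 2 others, and HBD, the delta-globin gene, by 0.10 (SE 0.19), which became -0.06 with the slide row as a block and -0.02 without LIN28B shRNA replicate 3. The adult list had a median of 0.10 and did not pass camera (adjusted p = 0.330), but by fry, which asks whether the genes move on balance in 1 direction, it was the 1 list of 32 to pass (adjusted p 0.0185). HBB is 1 of its 3 genes, and HBA2 and HBD did not rise with it. Its passing by fry therefore does not show that adult globins rose together.

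**Figure D3:**
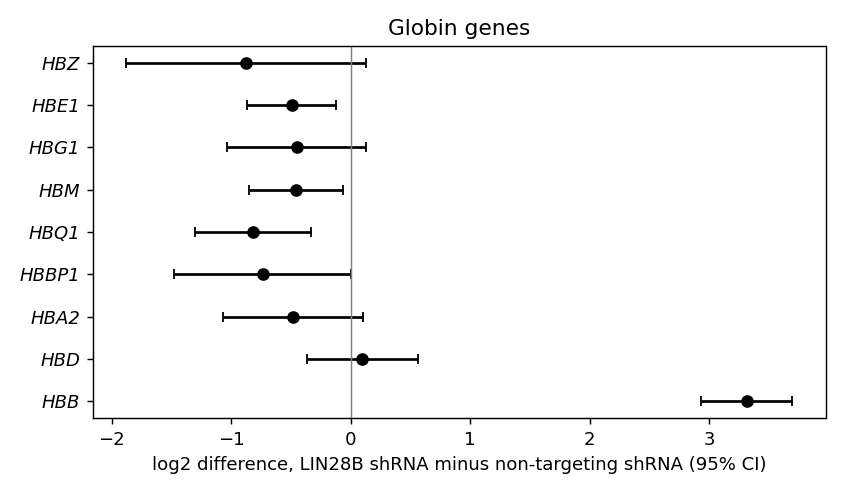
Log2 difference of each measured globin gene, LIN28B shRNA minus non-targeting shRNA (horizontal axis), with 1 probe per gene, where points are estimates from 3 arrays per group and bars are 95% confidence intervals. HBB stands at 3.31, and the 6 genes of the embryonic and fetal globin list lie between -0.88 and -0.45.

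Genes of the RNA handling and dissociation stress list, mostly immediate early transcription factors, were higher with the LIN28B shRNA. The median over 18 measured members was 0.47 (1.39-fold higher), with 13 higher and 5 lower, and the list passed camera (adjusted p 0.0316) but not with an estimated correlation (adjusted p = 0.693). JUN, a subunit of the AP-1 transcription factor, differed by 0.97 (SE 0.18) and was the 1 member past the threshold when adjusted over the list alone (adjusted p 0.0267), against 0 over all probes in limma and 8 higher at an unadjusted p under 0.05. EGR3, EGR2 and KLF6, which encode zinc-finger transcription factors, differed by 2.07 (SE 0.56), 1.31 (SE 0.37) and 0.72 (SE 0.21), and a second KLF6 probe by 0.25 (SE 0.37). The difference of the dim gene EGR3 was 0.93 and 1.15 with normexp background correction. Relative to all genes the median was 0.44, and it was 0.46 with quantile normalization and 0.52 with the slide row as a block, where the list did not pass (adjusted p = 0.0612 and 0.290). The adjusted p was 0.0707 and 0.0964 without LIN28B shRNA replicates 2 and 3, and 0.0952 and 0.0633 without control replicates 1 and 2. These genes also respond to how cells and RNA are handled before lysis, which the labels do not describe by sample.

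Lymphoid genes were lower as a list, with a median of -0.35 (1.27-fold lower) over 6 measured of 22, 5 of them lower. Relative to the control mean, the median member stood at -0.09, -0.54 and -0.49 on the LIN28B shRNA arrays. On the control arrays it stood at 0.10, -0.12 and 0.02, so LIN28B shRNA replicate 1 lay within the range of the controls. The list passed camera (adjusted p 0.00757) but not with an estimated correlation (adjusted p = 0.693). CD3G and CD3D, which encode chains of the T cell receptor complex, differed by -1.96 (SE 0.29) and -1.11 (SE 0.19). These were the 2 members past the threshold when adjusted over the list alone (adjusted p 0.00267 and 0.00286) and at an unadjusted p under 0.05, against 0 over all probes in limma. RAG1 differed by -0.35 (SE 0.18). With the slide row as a block the median relative to all genes was -0.41, against -0.37 without it, and the list did not pass (adjusted p = 0.214). It was -0.15 without a filter on dim probes (adjusted p = 0.376), which moved the median of all probes by -0.19.

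Ribosomal protein genes were lower by a small amount, with a median of -0.23 (1.17-fold lower) over 70 measured members, 59 of them lower. The list passed camera (adjusted p 4.27e-05) but not with an estimated correlation (adjusted p = 0.693), and 0 members passed when adjusted over the list alone, with 5 lower at an unadjusted p under 0.05 in limma. RPLP2 differed by -0.78 (SE 0.23), RPL8 by -0.33 (SE 0.13) and RPL11 by -0.45 (SE 0.17), and with the slide row as a block RPLP2 differed by -0.32 and RPL11 by -0.24. Control replicate 1 lay with the LIN28B shRNA arrays: relative to the control mean, the median member stood at -0.12, -0.21 and -0.27 on the LIN28B shRNA arrays, -0.22 on control replicate 1, and 0.08 and 0.19 on control replicates 2 and 3. Relative to all genes the median was -0.26, and it was -0.17 without control replicate 3, -0.38 without control replicate 1, -0.08 with quantile normalization (adjusted p = 0.358) and 0.02 with the slide row as a block (adjusted p = 0.680). Host genes of small nucleolar RNAs (snoRNAs) and growth-linked lncRNAs were lower too, with a median of -0.25 (1.19-fold lower) over 14 measured members, 11 of them lower (adjusted p 0.0163, 0.693 with an estimated correlation). All tested noncoding probes together had a median of -0.15. SNHG3 differed by -0.48 (SE 0.15), RMRP, the RNA of the mitochondrial RNA processing ribonuclease, by -0.85 (SE 0.29; -0.56 with the slide row as a block), SNHG7 by -0.40 (SE 0.15; 0.33, SE 0.41, at a second probe) and gene DANCR by -0.42 (SE 0.20; -0.22 without LIN28B shRNA replicate 2), with 0 members past the threshold when adjusted over the list alone and 3 lower at an unadjusted p under 0.05 in limma. The snoRNA host list passed in 14 of 24 alternatives. Relative to all genes its median was -0.28, and it was -0.16 with the slide row as a block (adjusted p = 0.506) and -0.19 with quantile normalization (adjusted p = 0.119). It also did not pass with normexp (adjusted p = 0.0940 and 0.147), without a filter on dim probes (0.131), without LIN28B shRNA replicate 2 (0.0562), without control replicate 3 (0.0832), with the mean of all probes of a gene (0.0629) or by fry (0.217).

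**Figure D4:**
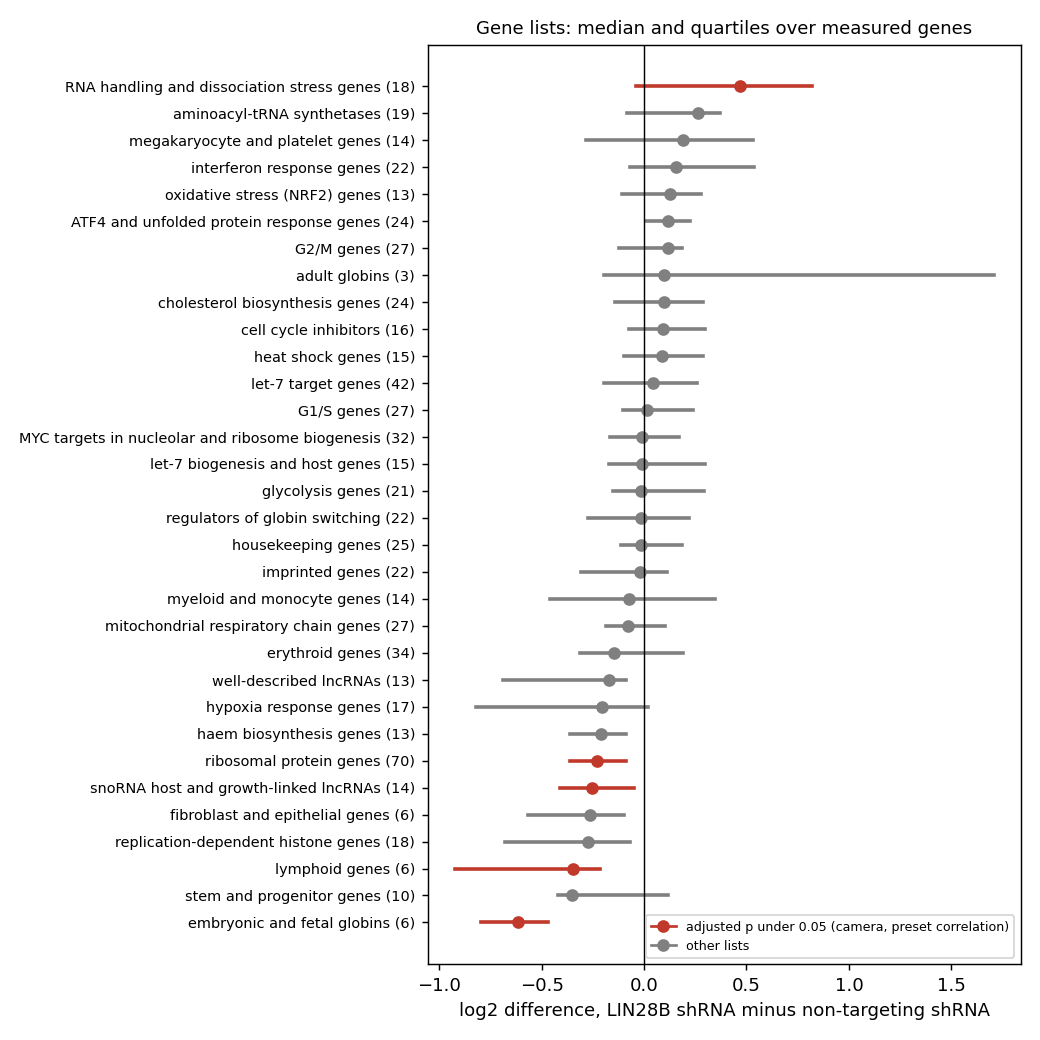
Median log2 difference of each of the 32 gene lists, LIN28B shRNA minus non-targeting shRNA (horizontal axis), where points are medians over the measured genes, bars run between the quartiles, and the number of measured genes is in brackets. The 5 lists that passed camera with a preset correlation are red: the stress list at 0.47 lies above 0, and the other 4 lie between -0.61 and -0.23. The ribosomal list lies at 0.02 relative to all genes with the slide row as a block.

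Neither list of the let-7 pathway that LIN28B acts on passed camera. The let-7 target genes had a median of 0.04 over 42 members (camera adjusted p = 0.952), and the let-7 biogenesis and host genes -0.01 over 15 (adjusted p = 0.949), the latter with a mean of 0.08, so that its mean and median differ in sign. Among the targets, 3 passed when adjusted over the list alone and 0 over all probes in limma, with 3 higher and 3 lower at an unadjusted p under 0.05. PBX3, a homeobox transcription factor gene, differed by 1.07 (SE 0.18) and FAS, a death receptor gene, by 0.93 (SE 0.16), both at an adjusted p of 0.0217 over the list alone (other probes gave 0.60 for PBX3 and 1.29 and 0.99 for FAS), and NR6A1, an orphan nuclear receptor gene, by -0.89 (SE 0.19) at 0.0384. HMGA2, a let-7 target that is also on the list of globin-switch regulators, differed by 1.29 (SE 0.55) at its brightest probe, but by 0.10 (SE 0.17) and 0.13 (SE 0.22) at its other 2 probes, and for the brightest probe of gene HMGA2 the difference was 0.10 with the slide row as a block and 0.75 without control replicate 2. IGF2BP1, on the same 2 lists, differed by -0.48 (SE 0.23; -0.73 with the slide row as a block).

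Of the blood-cell lists that did not pass camera, haem biosynthesis genes came nearest, with a median of -0.21 over 13 members (adjusted p = 0.0550). Erythroid genes had a median of -0.15 over 34 (adjusted p = 0.443), regulators of globin switching -0.01 over 22 (adjusted p = 0.606, mean 0.03), and KLF1, an erythroid transcription factor gene, differed by -0.55 (SE 0.23; -0.36 with the slide row as a block). Stem and progenitor genes had a median of -0.35 over 10 members (adjusted p = 0.330). LMO2, which encodes a bridging factor of erythroid and stem cell complexes, differed by -1.09 (SE 0.24) and was the 1 member of that list past the threshold when adjusted over the list alone (adjusted p 0.0367). Megakaryocyte and platelet genes had a median of 0.19 over 14 (adjusted p = 0.606), with the integrin gene ITGB3 at 1.92 (SE 0.40) and past the threshold over its list alone (adjusted p 0.0362), and at 1.23 with the slide row as a block. Myeloid and monocyte genes had a median of -0.07 over 14 (adjusted p = 0.499), and fibroblast and epithelial genes -0.26 over 6 (adjusted p = 0.443).

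Among the stress and signalling lists, hypoxia response genes had a median of -0.21 over 17 members (adjusted p = 0.0739). BNIP3, a mitophagy receptor gene, differed by -0.88 (SE 0.18), and the carbonic anhydrase gene CA9 by -2.29 (SE 0.43), both at an adjusted p of 0.0232 over the list alone. CA9 was above background on 2 of 3 LIN28B shRNA arrays, so the size of its difference is uncertain: it was -1.44 in the series matrix values, and -1.07 and -0.83 with normexp background correction. Interferon response genes had a median of 0.16 over 22 (adjusted p = 0.175) and moved both ways: adjusted over the list alone, 4 were higher and 2 lower, all at 0.0187, with OAS3 at 2.02 (SE 0.40) and IFI35 at 0.56 (SE 0.12) against IFIT1 at -0.70 (SE 0.15) and IFI6 at -0.71 (SE 0.16). With normexp background correction, the dim gene OAS3 stood at 0.97 and 1.18. ATF4 and unfolded protein response genes had a median of 0.12 over 24 (adjusted p = 0.330), oxidative stress genes 0.13 over 13 (adjusted p = 0.380), and heat shock genes 0.09 over 15 (adjusted p = 0.858).

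Growth and metabolism lists did not pass either. Replication-dependent histone genes had a median of -0.27 over 18 members (adjusted p = 0.0662), cell cycle inhibitors 0.09 over 16 (adjusted p = 0.330), G1/S genes 0.01 over 27 (adjusted p = 0.934) and G2/M genes 0.11 over 27 (adjusted p = 0.912). Aminoacyl-tRNA synthetases had a median of 0.26 over 19 (adjusted p = 0.330), and MYC targets in nucleolar and ribosome biogenesis -0.01 over 32 (adjusted p = 0.798). Mitochondrial respiratory chain genes had a median of -0.08 over 27 (adjusted p = 0.330), glycolysis genes -0.01 over 21 (adjusted p = 0.656) and cholesterol biosynthesis genes 0.10 over 24 (adjusted p = 0.656). Housekeeping genes had a median of -0.02 and a mean of 0.02 over 25 (adjusted p = 0.934).

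Imprinted genes, the class that includes H19, had a median of -0.02 over 22 measured of 35 and did not pass (adjusted p = 0.606). DIRAS3, a maternally imprinted tumour suppressor gene, differed by 1.14 (SE 0.19) and was the 1 member past the threshold when adjusted over the list alone (adjusted p 0.0200). MEG3 and DLK1, of another imprinted region, differed by -1.05 (SE 0.37) and -0.38 (SE 0.15). A second MEG3 probe differed by -0.06 (SE 0.23) and a second DLK1 probe by -0.27 (SE 0.22), and the first MEG3 probe by -0.64 with the slide row as a block. Well-described lncRNAs had a median of -0.17 over 13 measured of 31 (adjusted p = 0.380). MIR17HG, the host transcript of a microRNA cluster, differed by 1.00 (SE 0.18) and NORAD, a lncRNA that binds Pumilio proteins, by 0.79 (SE 0.16), past the threshold over the list alone (adjusted p 0.0142 and 0.0153), although a second NORAD probe differed by 0.01 (SE 0.21). Of 6462 tested noncoding probes, 0 passed in limma, and at an unadjusted p under 0.05 there were 364 higher and 1080 lower. Their median difference was -0.15, against 0.02 for the 20312 other probes, and -0.11 against 0.03 with quantile normalization.

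Some genes were well above background in all arrays of 1 group and on none of the other. In the LIN28B shRNA arrays alone, the largest bounds were those of IFIT1B, a relative of IFIT1 (at least 3.62-fold higher, adjusted p 0.0973 in limma), the pyrimidine receptor gene P2RY4 (at least 2.90-fold), PVALB (at least 2.56-fold), PLCH2 (at least 2.51-fold) and CD244 (at least 2.43-fold, and at least 1.29-fold at a second probe). In the control arrays alone they were those of the gastrin gene GAST (at least 7.17-fold lower with the LIN28B shRNA, adjusted p 0.251 in limma), which rests on control replicate 1 (at least 2.96-fold without it), LINC00861 (at least 3.56-fold), the cell adhesion gene L1CAM (at least 2.89-fold), CRB1 (at least 2.53-fold) and FOXS1 (at least 2.497-fold). The bounds allow for the dim signal of the other group, but not for the spread between arrays. With 1 array of the group above background left out, they ranged from 1.82 to 3.01 for CD244. The ranges were 3.12 to 4.45 for IFIT1B and 2.38 to 3.73 for L1CAM. None of these 10 genes passed over all probes in limma. All 10 had an unadjusted p under 0.05, which their selection by signal in 1 group only favours. Across all probes, 174 were above background in all LIN28B shRNA arrays only, and 41 in all control arrays only. The flag for background was set before scaling. Control replicates 2 and 3 were dimmer, with a 75th percentile of 376 and 330 against 515 to 549 on the other arrays. The gap between these counts therefore cannot be told apart from array brightness.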

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

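Alternatives chosen only after the data were seen were normexp on the median signal with either scaling, the percentile over detected probes, dark patches left out, and control replicates 2 and 3 averaged, with or without array weights. Of the alternative values of the LIN28B level and the H19 level, 21 of 22 each kept direction and side of the threshold. Of those of named genes 2517 did, 30 passed in the same direction, 9 missed the threshold and 5 reversed, and of those of lists 678 did, 15 passed, 29 missed and 46 reversed. Among the genes only HBB had passed, so all 9 misses were those of HBB, which passed in 13 of 22 alternatives. For every other named gene, LIN28B and H19 included, keeping the side of the threshold meant not passing again. Where no cause is given below, the cause was not tested.

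The count of probes past the threshold was 870 with array weights, 635 with the slide row as a block, 2 with the series matrix values, dark patches left out, or the mean of all probes of a gene, and 0 without a filter on dim probes, with the replicate block, with control replicates 2 and 3 averaged with or without weights, and at an adjusted p under 0.01, where 2718 to 6217 probes had an unadjusted p under 0.05 in limma, as in the fits without 1 array that gave 0. With the mean of all probes of a gene, the 2 were genes, out of 13492 tested. Over fits without 1 array the count of probes was 0 to 26, and 26 came without LIN28B shRNA replicate 1. Array weights and the slide row shared 31 probes, so the larger counts held mostly different probes. The count of 5 lists became 2 with quantile normalization, 3 without a filter, 0 with the slide row or an estimated correlation, and 3 to 7 without 1 array; by fry 0 of the 5 passed and 1 other list did, adult globins. That list holds HBB, whose rise its other measured members did not share. With array weights LIN28B differed by -1.11 and H19 by -1.81, both past the threshold, and without 1 array by -1.23 to -1.01 and -2.16 to -1.33, where the lowest adjusted p in limma was 0.0667 and 0.0514. Control replicate 2 had a weight of 4.13, and the other arrays had weights of 0.39 to 1.47. Neither gene passed with weights once control replicates 2 and 3 were averaged.

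The replicate number as a block assumes that equal numbers share a day or culture. Same-number arrays deviated from their group means without a common pattern (correlations across probes of 0.016, -0.0092 and 0.0077). A pairing that is small beside other differences between arrays could be missed, so whether the numbers pair the samples stays open. With the replicate block 0 probes and 5 lists passed.

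List values here are medians relative to all genes. With the slide row as a block, ribosomal protein genes stood at 0.019, G1/S genes at 0.018, adult globins at -0.0040, glycolysis genes at 0.046, housekeeping genes at 0.053, let-7 targets at -0.078, and the genes HBD at -0.059 and GCLM at -0.17. With array weights G1/S genes stood at 0.013 and let-7 targets at -0.034. With dark patches left out, G1/S genes stood at 0.0031, MYC targets at 0.028, heat shock genes at -0.0063 and let-7 targets at -0.0045. With the mean of all probes, let-7 biogenesis genes stood at 0.0062 and oxidative stress genes at -0.014. Without a filter, G1/S genes stood at 0.074, MYC targets at 0.052, glycolysis genes at 0.047, housekeeping genes at 0.044, imprinted genes at 0.022 and let-7 biogenesis genes at 0.051. With normexp and the 75th percentile, G1/S genes stood at 0.12, glycolysis genes at 0.016, housekeeping genes at 0.043, globin regulators at 0.061 and the gene MPO at -0.055. With normexp and quantile normalization, G1/S genes stood at 0.038, imprinted genes at 0.010, let-7 biogenesis genes at 0.039 and globin regulators at 0.012. With the series matrix values, G1/S genes stood at 0.026, let-7 biogenesis genes at 0.057 and globin regulators at 0.017. Without 1 array, the range was -0.015 to 0.049 for let-7 targets, -0.12 to 0.038 for let-7 biogenesis genes, -0.064 to 0.041 for G1/S genes, -0.12 to 0.014 for glycolysis genes, -0.055 to 0.16 for heat shock genes, -0.16 to 0.058 for imprinted genes, -0.058 to 0.22 for adult globins, -0.12 to 0.033 for globin regulators, -0.050 to 0.033 for housekeeping genes, -0.021 to 0.26 for gene HBD and -1.57 to 0.16 for gene KRT18. Of the lists past the threshold, embryonic and fetal globins passed in 21 of 24 alternatives, lymphoid genes in 20, ribosomal protein genes in 19, stress genes in 16 and snoRNA hosts in 14. Signal over background limits the dim probes: between 48.3% and 53.4% of probes were above background on an array.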

Other observations

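The splits of the arrays, the dark patches, the role of LIN28B shRNA replicate 1, both tests on HBB, the neighbour correlations within each group and the nearest-gene match of the ribosomal list were chosen only after the results they test were seen.

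HBB alone passed over all probes, while 4554 probes had an unadjusted p under 0.05. Splits of the arrays asked whether other groupings give as many calls, and 2 explanations for the low count were tested. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05: 2 gave at least 1 probe, the real one included and 1 the highest of the others, and 1 gave at least 5 lists, the highest other giving 4. Camera with the preset correlation thus also called lists in mixed groupings. Other splits with control replicates 2 and 3 on the same side gave 4, 2 and 4 lists, and those that parted them gave 0 or 1. At an unadjusted p under 0.05 the real split gave 4554 probes and the highest other 1668. Dark patches did not hide most changes, since 2 probes passed when they were left out. Leaving out LIN28B shRNA replicate 1 gave 26 probes against 0 for any other array, so that array may differ from the other 2 of its group. Among the probes higher with the slide row as a block, 38.8% lay in a dark patch of control replicate 1, against 2.32% of all tested probes, so the patches may account for part of them. Leaving the patches out also took many of these probes out of the test and subtracted local deviations from the remaining spots. How far the patches explain that count therefore stays open.

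The 5 lists were set against a trend of the change with signal level, using 10000 random lists matched in 20 level bins. The share of matched lists at least as far out was 0.04% for embryonic and fetal globins, 1.54% for lymphoid genes, 0.88% for snoRNA hosts and 0% for the stress list, which argues against a level trend as the whole cause of these 4. It was also 0% for ribosomal protein genes, but 61 of 70 members lie in the top 1% of level, so a bin mixes them with dimmer genes and that test decides nothing, a limit recognised only after its value was seen. Matched to the 20 genes nearest in level, 10.7% of lists were at least as low as the ribosomal list, with a matched median of -0.16, so a trend among the brightest probes may explain its shift. A biological effect of the LIN28B shRNA stays an untested hypothesis for the other 4, beside handling of cells and RNA for the stress list. None passed with the slide row as a block, which leaves 1 control array, but the medians relative to all genes were then -0.56 for the globins, -0.41 for lymphoid genes and 0.52 for the stress list, against -0.64, -0.37 and 0.44, and -0.16 against -0.28 for snoRNA hosts. Noncoding probes as a whole differed from other probes at matched level by a median of -0.15, so much of the snoRNA host shift may be one of noncoding probes in general, which the level test above, drawn from all genes, does not exclude.

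HBB was higher while the 6 measured genes of the embryonic and fetal globin list, a pseudogene among them, had lower estimates. None of those 6 passed over all probes in limma, and a second HBG1 probe differed by 0.17. As a list they passed camera with the preset correlation, but not with an estimated one (adjusted p = 0.693) nor by fry (adjusted p = 0.0889). Signal from another globin transcript would need one that rose as far, but the highest upper 95% limit among probes of the other globin genes was 1.04, below the lower limit of HBB at 2.93. A local fault is argued against by 5 HBB spots across the array, around which the largest local deviation on any array was 0.408 in size. What stays open, untested, is a shift from embryonic and fetal towards adult beta-globin when LIN28B is low, or cells that differed in HBB before the experiment. Among the measured adult globins only HBB clearly rose. Beside HBB at 3.31 stood HBD at 0.10, and HBA2, also an adult globin gene, was lower at each of its probes (-0.48, -0.79 and -0.80). The erythroid list stood at a median of -0.15 (camera adjusted p 0.443).

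A regional difference between the transduced cultures, such as in copy number, could make neighbouring genes change together. Across 13481 genes in chromosome order, which are not independent replicates, the Spearman correlation of changes 20 places apart was -0.00523, within 1000 shuffled orders (highest 0.0264). Direct neighbours correlated at 0.0417 (p = 0.001 by permutation, the smallest they can give), without a test of why. Between LIN28B shRNA replicate 1 and replicates 2 and 3 the correlations were 0.0714 at 1 place and 0.0414 at 5 places, above all shuffled orders (highest 0.0314 and 0.0241), and 0.0225 at 20 places (permutation p = 0.001, 0.001 and 0.008, highest shuffled 0.0326 at 20). Between control replicates 3 and 2 they were 0.00610, 0.0170 and 0.0116 (permutation p = 0.25, 0.026 and 0.091). A regional difference of that 1 array from its group therefore stays open.

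Genes outside the naming rule, chosen after their values were seen, had large differences that did not pass in limma. The tryptase genes TPSAB1 and TPSD1 differed by 3.28 and 3.21 (adjusted p 0.108 and 0.0973), and the histone gene H4C15 by -2.56 (adjusted p 0.120). Control replicates 2 and 3 correlated at 0.991 across probes, against 0.959 to 0.974 for every other pair. The control spike-ins stood 4.74 and 5.32 above the 75th percentile on these 2 arrays and 4.18 to 4.49 on the other 4.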
